A study of Mus musculus with 7 samples.

How the data were processed

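RNA of whole tibialis anterior muscle of 7-week-old male mice was sequenced at day 3 after injury with BaCl2, in 3 control libraries (genotype WT; Pax7-CreERT2) and 4 Sirt7 scKO libraries (genotype Sirt7fl/fl; Pax7-CreERT2). Per the labels, RNA was extracted with a column kit and libraries were made with the NEBNext Ultra RNA kit, which does not mark the strand of origin, and sequenced on a NovaSeq instrument. The submitters' processing notes name fastp, Bowtie2 and featureCounts and the genome build GRCm38 (mm10), without versions, roles or order. Bowtie2 does not align reads across introns, and whether it was run against the genome or against transcripts is not given. The settings for strand and for reads that align to several places, and the annotation release, are not given in the sources used here. The deposited values are counts, that is raw counts per gene and library, which was checked on the values: all were whole numbers with totals of 5425095 to 7553137 per library. Counting intervals given in the text cover counting error alone and leave out variation between animals. Reads without molecular identifiers are not independent molecules, which these intervals leave out too.

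The table held 48820 versioned Ensembl gene identifiers, of which 48058 matched GENCODE mouse release 21 (GRCm38) without the version and 40606 with the same version. The 762 that did not match held 0.25% of all counts. Of the protein-coding genes of that release, 98.78% were in the table, and 28443 identifiers had at least 1 count. Positions, strands and biotypes came from this release. Processed pseudogenes were aligned to protein-coding transcripts with BLAST 2.17.0, and the best hit over at least 80% of the copy was taken as the gene it derives from. Counts of near-identical copies and paralogs are uncertain, because the rule for reads that align to several of them is not given. Genes that overlap on opposite strands cannot be told apart in these counts.

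Groups followed the labels, and all 7 libraries were used. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16764. Libraries were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the Benjamini-Hochberg adjusted p taken at 0.05. The common dispersion was 0.0142, a biological coefficient of variation of 11.9%. The SE of a log2 fold change was its size divided by the square root of F. Expression levels are CPM with TMM factors. For the 6 genes named beforehand, the composition of libraries and list scores, two-sided exact permutation tests over the splits of 7 libraries into 3 and 4 were used, whose smallest p is 0.0286. For the 6 genes and the 34 list scores they were also adjusted by Benjamini-Hochberg, a step added after the results were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

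A set of 34 gene lists was fixed for cell types and processes of regenerating muscle and tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, where at least 5 members were tested. Fry's one-way test asks whether the genes of a list move on balance in 1 direction, its mixed test whether they change in either direction, and neither compares a list with other genes. Adjusted p-values were taken over the lists. Camera with a preset correlation of 0.01 and with an estimated correlation was an alternative. Beside the number of members past the threshold over all genes, the number past it when adjusted over the list alone was counted. Another 4 lists were added after the values were seen: osteoblast and osteocyte, cartilage, osteoclast, and regenerating fibre only.

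Genes were named by a rule. Sirt7, Pax7, Myod1, Myog, Myh3 and Mki67 were always named. Among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 10 with the largest change in each direction were named, leaving out symbols of predicted models and of pseudogenes. A direction with fewer than 5 was filled to 5 by the smallest unadjusted p. For each list described, the 2 to 4 members with the smallest unadjusted p were named. The tests, lists, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise.

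The alternatives were RLE, upper-quartile and total-count scaling, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma voom with and without sample quality weights, robust dispersion, the replicate number as a block, a fold threshold of 1.2, an adjusted p of 0.1, and leaving out each library. Testing protein-coding genes alone and adding the counts of processed copies to the genes they derive from were added after the values were seen. The test was also tried on simulated data with 16549 genes in the fit. It recovered 40.8% of 49 genes changed by a fold of 1.5, 81.6% of 49 by 2, 98% of 49 by 3 and all 50 by 4, and 12 unchanged genes made up 7.06% of its calls. Of 100 simulated lists of unchanged genes, 6 had a fry p under 0.05. Genes were simulated independently of each other and without structure among the libraries. These rates need not hold for the real data, where the mature fibre list, for example, had an estimated correlation of 0.734. No column of the table was left out.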

Results

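Gene expression was measured by RNA-seq in whole tibialis anterior (TA) muscle, a muscle at the front of the lower leg, of 7-week-old male mice at day 3 after injury with barium chloride (BaCl2). BaCl2 kills muscle fibres, which are then rebuilt by muscle stem cells. The 3 control libraries came from mice with Pax7-CreERT2 and wild-type Sirt7, and the 4 Sirt7 scKO libraries from mice with Pax7-CreERT2 and floxed Sirt7. Pax7-CreERT2 is a drug-inducible recombinase expressed in Pax7-positive cells, the stem cells of muscle, so the label scKO denotes deletion in that lineage, while the RNA came from all cells of the muscle. The labels name the libraries of a group as separate biological replicates. Total counts per library ran from 5601699 to 5777563 in the 3 control libraries and from 5425095 to 7553137 in the 4 Sirt7 scKO libraries (two-sided exact permutation p = 0.143). All levels below are CPM, counts scaled by the library's counts in tested genes and its TMM factor, as mean ± SD over these 3 and 4 libraries, and all fold changes are Sirt7 scKO over control on the log2 scale with the standard error (SE) of the fit.

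The series asks how loss of SIRT7 changes gene expression while muscle regenerates, and the design gives 1 comparison, Sirt7 scKO against control. Ibsp, Mmp13 and Alpl, genes of bone matrix, collagen breakdown and mineralisation, were higher in every Sirt7 scKO library than in any control library. The stress cytokine gene Gdf15 and the histocompatibility gene H2-Q1 were lower in the same way. None of the 34 gene lists for cell types and processes of regenerating muscle passed the one-way test of limma's fry, with 4 at an unadjusted p under 0.05.

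Sirt7, a NAD-dependent deacylase of the sirtuin family (ENSMUSG00000025138.14, GRCm38 chromosome 11, 120618372 to 120625240, minus strand), was read first as a check of the labels. Its level was 46.2, 70.6 and 57.3 CPM in control replicates 1 to 3 and 39.7, 34.1, 47.9 and 52.97 CPM in Sirt7 scKO replicates 1 to 4. The means were 58.0 ± 12.2 CPM and 43.7 ± 8.39 CPM, and the ranges of the groups overlapped. The log2 fold change was -0.42 (SE 0.162, 95% interval -0.77 to -0.07), with an edgeR adjusted p of 0.288 and a two-sided exact permutation p of 0.143 on CPM. The difference did not pass either test, although the interval for this gene alone excluded 0. Counts covered the whole gene in whole muscle, so they neither follow the floxed part alone nor the stem cells alone.

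Ibsp, Mmp13 and Alpl were higher in Sirt7 scKO muscle. Ibsp (ENSMUSG00000029306.8, chromosome 5, 104299171 to 104311469), which encodes the bone matrix protein integrin-binding sialoprotein, had 2, 1 and 0 counts in the control libraries and 83, 56, 88 and 22 counts in the Sirt7 scKO libraries. The pooled counts gave a ratio of 52.9 with an exact 95% counting interval of 17.9 to 258, and the edgeR adjusted p was 0.00999. Mmp13 (ENSMUSG00000050578.9, chromosome 9, 7272514 to 7283331), a collagenase, rose from 13.0 ± 5.76 to 62.4 ± 18.5 CPM (log2 fold change 2.27, SE 0.276, edgeR adjusted p = 0.00999). Alpl (ENSMUSG00000028766.10, chromosome 4, 137741733 to 137796384), the tissue-nonspecific alkaline phosphatase, rose from 1.34 ± 0.716 to 6.92 ± 1.12 CPM (log2 fold change 2.35, SE 0.337, edgeR adjusted p = 0.0191). In each of the 3 genes every Sirt7 scKO library lay above every control library. Without control replicate 2 the edgeR adjusted p of each was 0.111. Mmp13 also missed the threshold with robust dispersion (edgeR adjusted p = 0.113). Ibsp also missed it without control replicate 1 (edgeR adjusted p = 0.0535), where the pooled ratio became 105 (exact 95% counting interval 18.7 to 4170), since 1 control count remained. Without control replicate 3 the pooled ratio of Ibsp was 35.2 (11.9 to 172). Alpl also missed it without control replicate 1 or Sirt7 scKO replicate 3 (edgeR adjusted p = 0.0672 and 0.0843).

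The stress-induced cytokine gene Gdf15 and the class I major histocompatibility gene H2-Q1 were lower in Sirt7 scKO. Gdf15 (ENSMUSG00000038508.7, chromosome 8, 70629393 to 70632456) fell from 27.8 ± 5.66 to 12.7 ± 1.91 CPM (log2 fold change -1.12, SE 0.164, edgeR adjusted p = 0.0206). H2-Q1 (ENSMUSG00000079507.10, chromosome 17, 35320405 to 35325099) fell from 37.3 ± 2.43 to 18.9 ± 3.12 CPM (log2 fold change -0.99, SE 0.134, edgeR adjusted p = 0.0152). H2-Q1 belongs to a family of near-identical class I genes, between which short reads can be divided, so its count is uncertain. Both missed the threshold without control replicate 1 (edgeR adjusted p = 0.0672 for Gdf15 and 0.0724 for H2-Q1) and without control replicate 2 (edgeR adjusted p = 0.156 and 0.145). Gdf15 also missed it without Sirt7 scKO replicate 3 (edgeR adjusted p = 0.069). The mitochondrial lysine tRNA gene mt-Tk (ENSMUSG00000064355.1, mitochondrial genome, 7700 to 7764) rose from 11.5 ± 3.25 to 79.7 ± 43.3 CPM (log2 fold change 2.80, SE 0.471, edgeR adjusted p = 0.043), with 19.3 CPM in Sirt7 scKO replicate 4 against 82.6 to 121 CPM in the other Sirt7 scKO libraries. It missed the threshold when control replicate 1, 2 or 3 or Sirt7 scKO replicate 2 or 3 was left out, with edgeR adjusted p from 0.0586 to 0.258. It also missed it with limma voom (adjusted p = 0.160), with robust dispersion (edgeR adjusted p = 0.238) and with copies added to the genes they derive from (edgeR adjusted p = 0.0836). Whether reads at mt-Tk, which is 65 bases long, came from the tRNA or from longer transcripts over it was not tested.

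The genes added in each direction to fill the naming rule did not pass the threshold in the main test. Each passed in some alternatives (mt-Ti in 10 of 18, Actn3 and Tppp3 in 10 of 19, Dapk3 in 7 of 19). In the positive direction this was the mitochondrial isoleucine tRNA gene mt-Ti (14.3 ± 6.65 against 46.7 ± 14.98 CPM, log2 fold change 1.71, edgeR adjusted p = 0.05005). In the negative direction these were Actn3, the alpha-actinin of fast fibres (185 ± 67.1 against 62.0 ± 27.6 CPM, log2 fold change -1.57, edgeR adjusted p = 0.0519), Tppp3 (33.5 ± 6.86 against 19.3 ± 1.66 CPM, log2 fold change -0.80, edgeR adjusted p = 0.0559) and the kinase gene Dapk3 (39.7 ± 2.82 against 26.7 ± 1.82 CPM, log2 fold change -0.57, edgeR adjusted p = 0.0561).

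**Figure D1:**
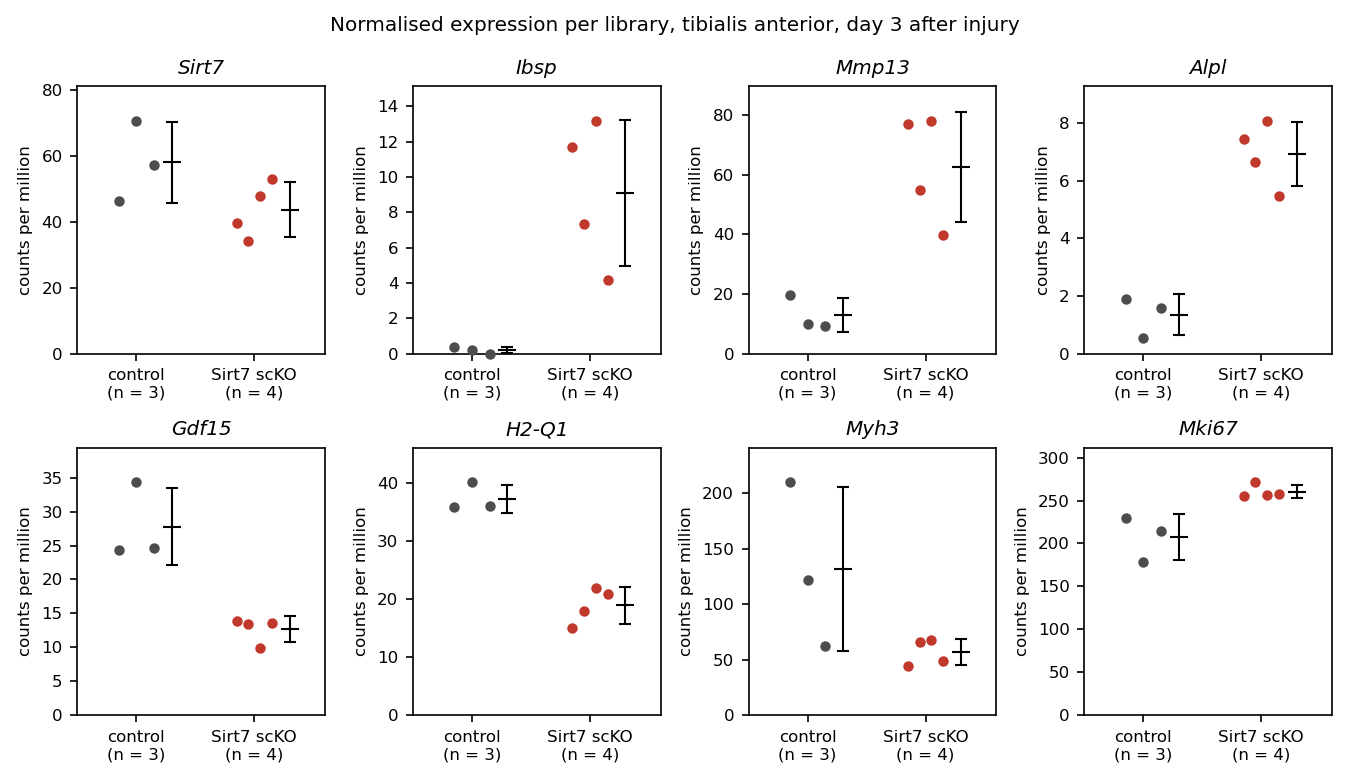
Normalised expression of 8 genes in each library, in CPM on linear axes that start at 0, with grey points for the 3 control and red points for the 4 Sirt7 scKO libraries and black bars for mean ± SD. Ibsp, Mmp13 and Alpl lay higher and Gdf15 and H2-Q1 lower in every Sirt7 scKO library than in any control library, while the groups overlapped for Sirt7 and Myh3 and the Mki67 difference did not pass the test over all genes.

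Of 16764 genes tested, 22 passed an edgeR adjusted p of 0.05, 17 higher and 5 lower in Sirt7 scKO, and the groups did not overlap in any of the 22. The balance turned without control replicate 3 (15 higher and 41 lower), without Sirt7 scKO replicate 1 (38 and 146) and without Sirt7 scKO replicate 4 (132 and 198). Protein-coding genes made up 6 of them, and 12 were processed pseudogenes, intronless copies of other genes. Processed pseudogenes were 54.5% of the genes past the threshold and 11.2% of those tested (Fisher's exact odds ratio 9.56, two-sided p = 8.3e-07, across genes, which are not independent replicates). The 12 copies had a median identity of 97.3% to the gene they derive from, and 10 derived from cytosolic ribosomal protein genes, so reads can be divided between them and their relatives and their counts are uncertain. Bowtie2, named in the processing notes, does not align reads across introns. If reads were aligned to the genome, reads of spliced genes that cross introns can be counted at intronless copies, and Rpl36a-ps2 stood at 250.7 CPM against 2.98 CPM for Rpl36a. Their log2 fold changes ran from -0.97 to 1.82. Named after their values were seen, because they fall outside the naming rule, the remaining genes past the threshold were the protein-coding model Gm10260 and the overlapping long noncoding RNA Gm26619 (both log2 fold change 0.48), Gm10252 (0.61), which overlaps Ftl1 on the other strand, and Gm45091 (-0.61), which is antisense to Cebpa. These overlapping pairs cannot be separated without strand. Gm10260 and Gm26619 both stood at 141.9, 147.7 and 134.5 CPM in control replicates 1 to 3, which points to the same reads counted at both. Their calls are therefore not separate observations. At an unadjusted p under 0.05 there were 2284 genes, against 838 by chance, and the groups did not overlap in 12.2% of tested genes, against 5.71% by chance. No gene passed without control replicate 2 and 330 passed without Sirt7 scKO replicate 4, DESeq2 passed 154, and 4 of the 35 divisions of the 7 libraries into 3 and 4, the real one included, gave 22 genes or more. Testing protein-coding genes alone left 5 genes, Ibsp, Mmp13, Alpl, Gdf15 and H2-Q1.

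**Figure D2:**
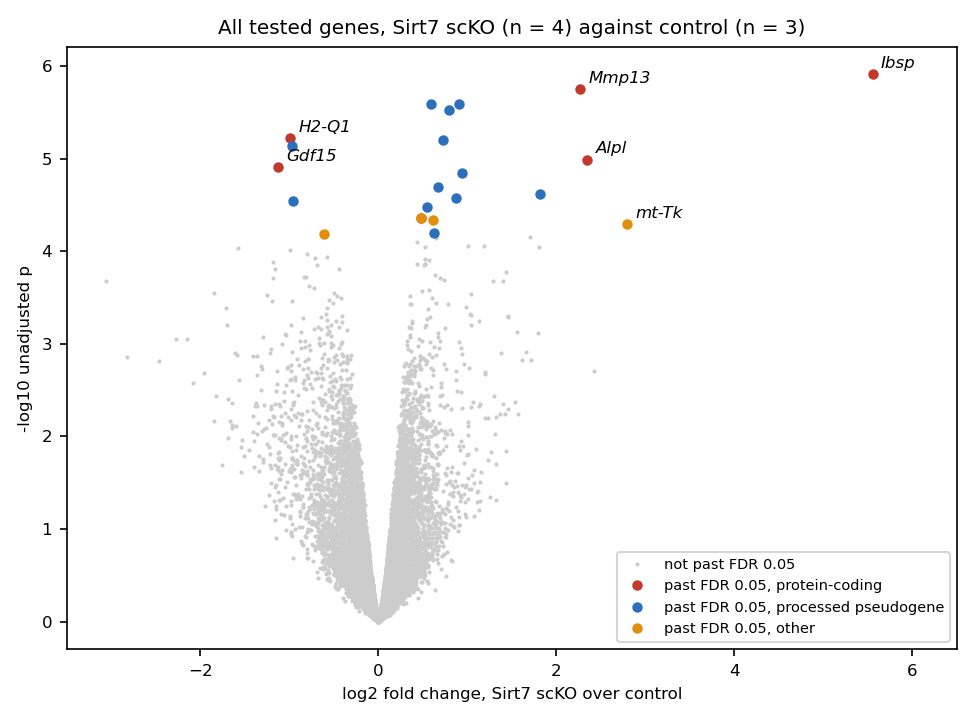
Each of the 16764 tested genes by log2 fold change (Sirt7 scKO over control) and by -log10 of the unadjusted edgeR p, with the 22 genes past an adjusted p of 0.05 coloured by kind. Processed pseudogenes, in blue, account for 12 of the 22, and Ibsp has the largest fold change.

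Genes of muscle fibres had negative fold changes in Sirt7 scKO, but the control libraries differed among themselves by as much. In the mature fibre list all 29 tested genes were negative, with a median log2 fold change of -1.05. None passed over all genes and 16 passed, all lower, when adjusted over the list alone. Limma's fry gave an adjusted p of 0.384 for the list. The members with the smallest p were Actn3, the fast and intermediate myosin Myh2 (89.5 ± 92.3 against 10.6 ± 6.85 CPM) and the calcium release channel Ryr1 (127 ± 45.9 against 61.3 ± 20.7 CPM). The list score, the mean centred log2 CPM, was 1.39, 0.84 and -0.03 in control replicates 1 to 3 and 0.54, -1.52, -0.64 and -0.58 in Sirt7 scKO replicates 1 to 4. In the list of embryonic and neonatal fibre genes, which new fibres express, 12 of 14 genes were negative (median -0.86, fry adjusted p = 0.426), with 11 lower and 1 higher adjusted over the list alone and none over all genes. Actc1 was 96.6 ± 57.5 against 39.3 ± 7.27 CPM, Csrp3 47.7 ± 44.1 against 9.74 ± 6.36 CPM, and the embryonic myosin Myh3 131 ± 74.1 against 56.7 ± 11.9 CPM (log2 fold change -1.21, SE 0.29, edgeR adjusted p = 0.124). Control replicate 3 had 62.7 CPM of Myh3, inside the Sirt7 scKO range of 44.5 to 67.5 CPM. For myogenic commitment and fusion, 17 of 19 genes were negative (median -0.28, fry adjusted p = 0.426), with 1 gene, the acetylcholine receptor anchor Rapsn, lower adjusted over the list alone (32.1 ± 3.23 against 22.2 ± 2.55 CPM), and Klhl41 at 110 ± 52.4 against 52.1 ± 26.1 CPM. The differentiation factor Myog was 211 ± 86.9 against 148 ± 42.4 CPM (log2 fold change -0.51, SE 0.249, edgeR adjusted p = 0.391), and the myogenic determination factor Myod1 was 221 ± 37.7 against 206 ± 29.2 CPM (log2 fold change -0.10, SE 0.127, edgeR adjusted p = 0.771), which became 0.04 without control replicate 1.

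Neither Pax7 nor the stem cell list passed the test. The stem cell factor Pax7 was 11.5 ± 0.716 against 12.4 ± 3.42 CPM (log2 fold change 0.13, SE 0.21, 95% interval -0.33 to 0.58, edgeR adjusted p = 0.83). In the muscle stem cell list 6 of 18 genes were positive (median -0.09, fry adjusted p = 0.887), none past the threshold over all genes or adjusted over the list alone. The smallest p belonged to the integrin Itga7 (240 ± 49.9 against 186 ± 18.1 CPM), the receptor Fgfr4 (44.3 ± 8.42 against 32.4 ± 6.3 CPM) and, in the other direction, the myogenic factor Myf5 (10.7 ± 0.389 against 14.5 ± 2.93 CPM, groups not overlapping). The sirtuin list had 2 of 7 genes positive (median -0.03, fry adjusted p = 0.828), led by Sirt7 and by Sirt2 (log2 fold change -0.13). Growth factors that act on stem cells had 11 of 19 genes positive (fry adjusted p = 0.97), led by Metrnl (-0.31) and Pdgfa (-0.25), and their median of 0.03 differed in sign from their mean of -0.05.

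Cell cycle genes had mostly positive fold changes of small size. In the mitosis list 25 of 28 genes were positive (median 0.19, fry adjusted p = 0.379), with 3 higher and 1 lower adjusted over the list alone and none over all genes. The mitosis score did not overlap between the groups, with a two-sided exact permutation p of 0.0286, the smallest possible here, and 0.324 adjusted over the 34 lists. Nusap1, a spindle protein gene, was 27.6 ± 0.435 against 36.6 ± 2.01 CPM, the proliferation marker Mki67 207 ± 26.5 against 260 ± 7.43 CPM (log2 fold change 0.33, SE 0.092, edgeR adjusted p = 0.173, two-sided exact permutation p = 0.0286, 0.172 adjusted over 6 genes fixed beforehand), and the ubiquitin-conjugating enzyme gene Ube2c 167 ± 68.6 against 82.7 ± 38.9 CPM. Ube2c, the 1 lower gene, overlaps the fibre gene Tnnc2 on the other strand (140 ± 67.4 against 53.4 ± 40.4 CPM, singled out after its values were seen), and reads of the pair cannot be separated without strand. In the DNA replication list 25 of 32 genes were positive (median 0.14, fry adjusted p = 0.384), none past the threshold over all genes or adjusted over the list alone, with Ccne2 at 0.45 (SE 0.143) and Tyms at 0.59 (SE 0.196). Fry's test for change in either direction passed for 2 lists, DNA replication (adjusted p = 0.0453) and p53 targets and senescence (adjusted p = 0.0442). The second held 13 negative and 10 positive genes (median -0.05, one-way fry adjusted p = 0.384), with Gdf15 lower over all genes and Gdf15, Phlda3 (88.2 ± 7.73 against 60.3 ± 8.13 CPM) and Eda2r (25.3 ± 2.49 against 18.7 ± 2.46 CPM) lower adjusted over the list alone.

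No list of inflammatory or stromal cells passed. In the neutrophil list 4 of 6 tested genes were positive (median 0.66, fry adjusted p = 0.379), and these 4, Mmp9 (42.5 ± 1.33 against 81.3 ± 27.3 CPM), S100a9 (1.29 ± 0.704 against 3.41 ± 1.1 CPM), S100a8 and Clec4d, were higher adjusted over the list alone and not over all genes. Mmp9 encodes a gelatinase that other cells also make. Without Sirt7 scKO replicate 4, whose neutrophil score of -0.10 lay beside the -0.11 of control replicate 3, the list passed with an adjusted p of 0.0342. In the monocyte and macrophage list 12 of 25 genes were positive (median -0.02, mean 0.05, fry adjusted p = 0.97), led by the phagocytic receptor Mertk (log2 fold change 0.46, SE 0.125) and Trem2 (-0.27, SE 0.097). In the fibro-adipogenic progenitor list, the resident fibroblast-like cells of muscle, 16 of 19 genes were negative (median -0.14, fry adjusted p = 0.379), with Dpt (95.3 ± 14.8 against 67.0 ± 10.2 CPM) and Cd248 (121 ± 1.72 against 95.6 ± 12.6 CPM) lower adjusted over the list alone. Extracellular matrix genes were positive in 18 of 29 cases (median 0.04, fry adjusted p = 0.911), led by Col11a1 (0.93) and Col12a1 (0.39).

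Immediate early and heat shock genes were negative in 17 of 18 cases (median -0.32, fry adjusted p = 0.379), with 9 lower adjusted over the list alone and none over all genes. Junb was 140 ± 8.04 against 110 ± 8.65 CPM, Jund 198 ± 23.5 against 129 ± 34.6 CPM and the heat shock gene Hspa1a 34.5 ± 5.32 against 17.3 ± 8.37 CPM. These genes respond within minutes to handling as well as to growth signals. Sirt7 scKO replicate 4 had a score of 0.12, against -0.29 to -0.26 in the other Sirt7 scKO libraries and 0.20 to 0.29 in control, and without it the list passed with an adjusted p of 0.0112.

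**Figure D3:**
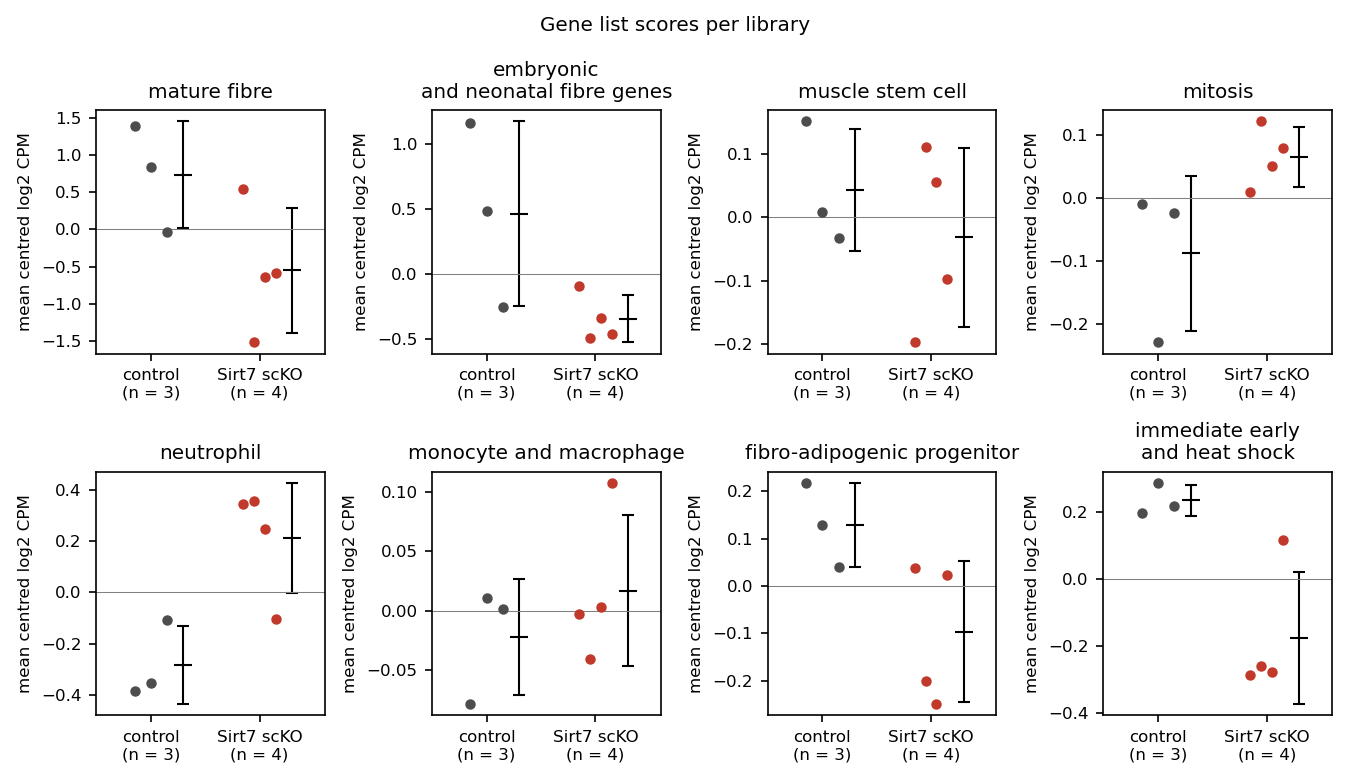
Score of 8 gene lists in each library (mean over the list's genes of log2 CPM centred on each gene's mean over all libraries), with grey points for the 3 control and red points for the 4 Sirt7 scKO libraries and black bars for mean ± SD. Fibre scores spread widely among the control libraries (mature fibre 1.39 to -0.03), and Sirt7 scKO replicate 4 stands apart for immediate early and heat shock genes at 0.12.

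Energy metabolism and stress lists did not pass. Glycolysis and glycogen genes were negative in 19 of 21 cases (median -0.22, fry adjusted p = 0.426), with Pgam2 at -0.93 and Gys1 at -0.50. Their score was 0.34, 0.21 and 0.03 in control replicates 1 to 3 and 0.28, -0.39, -0.32 and -0.16 in Sirt7 scKO replicates 1 to 4, beside the mature fibre scores given above. Negative values were also found for oxidative phosphorylation genes in 26 of 42 (median -0.05, fry adjusted p = 0.887), with Ndufa2 at -0.64 and Uqcrq at -0.37. Fatty acid oxidation genes were positive in 10 of 19 cases (median 0.005, fry adjusted p = 0.97), with Cd36 at 0.37 and Slc25a20 at 0.41. Unfolded protein response genes were positive in 18 of 23 cases (median 0.09, fry adjusted p = 0.426), with Dnajb9 at 0.39 and Dnajc3 at 0.23. Autophagy and atrophy genes were negative in 10 of 16 cases (median -0.09, fry adjusted p = 0.887), with Bnip3 at 0.51 higher and Trim55 at -0.70 lower adjusted over the list alone. Circadian clock genes were negative in 11 of 15 cases (median -0.22, fry adjusted p = 0.426), with Dbp at -0.77 lower adjusted over the list alone and Nr1d1 at -0.37. Their score did not overlap between the groups either (two-sided exact permutation p = 0.0286, 0.324 adjusted over the 34 lists). Ribosome biogenesis genes were positive in 23 of 35 cases (median 0.12, fry adjusted p = 0.565), with Npm1 at 0.35 and Nop56 at 0.29. Cytosolic ribosomal protein genes had 22 of 45 positive (fry adjusted p = 0.97), with Rpl6 at 0.58 higher adjusted over the list alone and Rpl3 at 0.31, and their median of -0.005 differed in sign from their mean of 0.004 and from the median under upper-quartile scaling. Some of these genes stood at few CPM, such as Rps27 at 2.41 ± 0.584 CPM in control (singled out after its values were seen), and reads counted at their copies are not in these values. Mitochondrial ribosomal protein genes had 14 of 30 positive (median -0.03, fry adjusted p = 0.97), with Mrpl16 at 0.29 and Mrps12 at -0.28. Targets of TGF beta and BMP were negative in 14 of 18 cases (median -0.05, fry adjusted p = 0.565), with Id2 at 0.29 and Pmepa1 at -0.24.

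The remaining lists gave small medians, except erythroid genes. Interferon response genes were positive in 16 of 22 cases (median 0.11, fry adjusted p = 0.911), with Mx1 at 0.60 higher adjusted over the list alone and Ifit1 at 0.54. Pro-inflammatory cytokine genes had 9 of 18 positive (median -0.002, positive under upper-quartile scaling, fry adjusted p = 0.97), with Ccl8 at -0.76 lower adjusted over the list alone and Ccl5 at -0.80. The lymphocyte list had 3 of 12 positive (median -0.18, fry adjusted p = 0.887), with Klrb1c at 0.87 and Foxp3 at -0.29. The dendritic and mast cell list had 7 of 17 positive (median -0.08, fry adjusted p = 0.97), with Ccr7 at -1.21 and Cpa3 at 0.97. Endothelial genes had 13 of 20 positive (median 0.04, fry adjusted p = 0.94), with Vwf at -0.36 and Tek at -0.33. Pericyte and smooth muscle genes had 8 of 14 positive (median 0.09, fry adjusted p = 0.911), with Des, which muscle fibres also express, at -0.89 lower and Pdgfrb at 0.30 higher adjusted over the list alone. Adipocyte genes had 6 of 10 positive (median 0.05, fry adjusted p = 0.935), with Fabp4 at 0.41 higher adjusted over the list alone and Car3 at -0.62. Schwann and nerve genes had 6 of 13 positive (median -0.06, fry adjusted p = 0.97), with Cadm3 at -0.53 and Scn7a at 0.20. Tenocyte genes had 6 of 12 positive (median 0.03, mean -0.01, fry adjusted p = 0.97), with Scx at -0.62 lower adjusted over the list alone and Thbs4 at -0.28, which became 0.03 without control replicate 1. Erythroid genes had 5 of 6 positive (median 1.07, fry adjusted p = 0.588), with Hba-a1 (28.4 ± 0.624 against 66.5 ± 46.7 CPM) and Alas2 higher adjusted over the list alone, and with Sirt7 scKO replicate 3 at a score of 1.37 against -0.34 to 0.145 in the other Sirt7 scKO libraries.

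Over the 34 lists, 0 passed fry's one-way test at an adjusted p of 0.05 and 4 had an unadjusted p under 0.05 (fibro-adipogenic progenitor, immediate early and heat shock, mitosis and neutrophil). Limma's camera with a preset correlation passed 12 lists, led by mature fibre, and with an estimated correlation it passed 0, with 0 at an unadjusted p under 0.05 and adjusted p of 0.632 or 0.852 for those 12.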

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

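The tests below of bone, cartilage, processed pseudogenes, the strain region and fibre concern patterns found in the main test. They were therefore chosen after its results were known. The tests of mature osteoblasts and of reads shared within families, and the marker lists used for bone, cartilage and fibre, were also chosen only after the results were seen, as was the reading of the bone and cartilage lists by their level in control and of single bone and cartilage genes. Of 59 measures per library, 6 had 1 Sirt7 scKO library far from the others, with a gap to the nearest above Dixon's 95% critical share of the group's range, which chance gives in about 1 of 20 measures.

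The split of the 7 libraries into 3 control and 4 Sirt7 scKO gave 22 genes past the threshold, and 4 of the 35 splits, the real one included, gave as many, so chance is not excluded. The highest other split, Sirt7 scKO replicates 1 to 3 against the rest, gave 245 genes, which points to a structure of the samples. It differs from the real split in the place of Sirt7 scKO replicate 4 alone, so it holds much of the genotype contrast too. Control replicates 1 and 2 with Sirt7 scKO replicate 1 against the rest gave 154, and Sirt7 scKO replicates 2 to 4 against the rest gave 92. The split with 92 differs from the real one in the place of Sirt7 scKO replicate 1 alone. The split with 154 exchanges control replicate 3 and Sirt7 scKO replicate 1. Both therefore hold part of the genotype contrast too.

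Ibsp, Mmp13 and Alpl were higher in Sirt7 scKO, with Ibsp at 249 counts over the 4 libraries against 3 in control. Bone and cartilage caught in the dissection stay open. Their lists had median log2 fold changes of 0.12 (95% bootstrap interval 0.045 to 0.477, score exact p = 0.0571) and -0.235 (-0.497 to -0.007, score exact p = 0.171). Both lay under the bound of 0.5, which was written before these medians were computed. But all 11 and all 5 of their tested genes stood at 1 CPM or more in control, which would hide a small share. Cartilage genes of low count went apart in their pooled counts. Col2a1 and Col10a1 had 19 counts in either group (ratio per library size 0.639, 95% counting interval 0.32 to 1.27). Acan had 50 counts against 16 (ratio 2, 95% counting interval 1.12 to 3.75). Per library, Acan had 7, 3 and 6 counts in control replicates 1 to 3 and 6, 21, 17 and 6 in Sirt7 scKO replicates 1 to 4, so the groups overlapped. Mature osteoblasts stay open too. Bglap (17 counts against 2, ratio per library size 5.43, 95% counting interval 1.29 to 48.4) and Bglap2 (3 against 3) reached 0.0803 counts per count of Ibsp (0.0482 to 0.127), an interval that crosses the bound of 0.1. Of other bone genes of low count, ratios per library size were 1.21 (0.689 to 2.2) for Sp7, 0.987 (0.625 to 1.58) for Dmp1, 1.06 (0.54 to 2.17) for Phex and 1.08 (0.56 to 2.14) for Ifitm5. Dlx5 had 0, 2 and 0 counts in control replicates 1 to 3 and 3, 10, 7 and 0 in Sirt7 scKO replicates 1 to 4. Tnfrsf11b had 1, 4 and 2 against 1, 8, 6 and 6. Mepe (0 counts against 2) and Sost (0 in either group) were too few to compare. In the bone list 9 of 11 tested genes were positive, led by Tnfsf11 at 0.99 (edgeR adjusted p = 0.321). An effect of the genotype on cells that express Ibsp, Mmp13 and Alpl may also account for their values and was not tested.

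Processed pseudogenes made up 12 of the 22 genes past the threshold. The summed families argue against a change of parent genes or whole families as large as that of the called copies as the common cause. Over the reads that were counted, the families' median log2 fold change, signed by the copy's direction, was 0.227 (95% bootstrap interval 0.113 to 0.3) against 0.837 for the copies. The copies were selected by their test, which raises their median, and reads that align to several places may be missing. A smaller change of the families in the copies' direction stays open. The families of Rpl36a (0.62) and Npm1 (0.42) moved by more than 0.5 of their copies, but Rpl36a-ps2 alone held 250.7 of the 253.8 CPM of its family. The Rpl32 family (-0.119) entered this median under both Gm7266 and Gm7434, which had opposite directions. The parent genes alone had 0.083 (-0.198 to 0.267), which decides less, since reads that cross introns may be counted at the copies. All tested processed copies had a median of 0.082 (0.068 to 0.093), against 0.007 for all tested genes and 0.699 for the called copies. The called copies were selected by their test, so this comparison cannot decide whether a small shift of all copies contributed. The share of counts at processed pseudogenes was higher in every Sirt7 scKO library than in any control library (13.36 to 14.412% against 13.083 to 13.267%). Within 10 Mb of Sirt7 lay 0 of the 22 genes (95% interval 0 to 15.4%, edgeR) and 196 of the 16764 tested genes. Of those 196, 33 had an unadjusted p under 0.05, as had 2284 of all 16764 tested genes. The called genes thus lie outside such a region of another strain around the floxed allele, and strain differences elsewhere were not tested. Reads moving between near-identical members stay open, as does an untested difference in sequence between the animals at such copies: the rest of each family had a median of 0.108 (-0.23 to 0.183), and the Rpl32 copies Gm7266 (0.88) and Gm7434 (-0.95), singled out after their values were seen, went opposite ways.

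Fibre genes were negative in Sirt7 scKO, and control replicate 3 lay with the Sirt7 scKO libraries. Unequal amounts of fibre that survived the injury cannot be told apart from slower rebuilding: with the mature fibre score as a covariate, the score of genes of regenerating fibre differed by -0.30 (95% interval -1.41 to 0.81), and without it by -0.55. The 7 libraries leave that interval too wide to decide. In the regenerating fibre list 1 of 12 genes was positive, with a median of -0.59 (-0.94 to -0.33, score exact p = 0.0857). A slower rebuilding in Sirt7 scKO may account for the values and stays open as untested.

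The mitochondrial share of counts was 2.34% in Sirt7 scKO replicate 2 against 2.78% to 2.84% in the other 3, a gap of 0.882 of the range. The haemoglobin share was 0.049% in Sirt7 scKO replicate 3 against 0.011% to 0.016%, a gap of 0.868. The pro-inflammatory cytokine score was 0.077 in Sirt7 scKO replicate 4 against -0.065 to -0.044, a gap of 0.852. The immediate early and heat shock score was 0.118 in Sirt7 scKO replicate 4 against -0.286 to -0.26, a gap of 0.936. The Mki67 level was 271 CPM in Sirt7 scKO replicate 2 against 255 to 258 CPM, a gap of 0.834. The Gdf15 level was 9.88 CPM in Sirt7 scKO replicate 3 against 13.5 to 13.9 CPM, a gap of 0.888.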

How the results depend on the processing

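The alternatives with protein-coding genes alone and with copies added to the genes they derive from were chosen only after the results were seen. All 22 genes kept their direction in every alternative that tested all of them. RLE scaling (22), voom (23), upper-quartile scaling (33, 9 of them lower) and a mean of 1 CPM (31) gave counts within 1.5 times of 22 in total. Total-count scaling gave 35 genes, 10 of them lower. The total, higher and lower counts were 585, 209 and 376 with no filter, where the prior degrees of freedom were 106.4 against 7.9. With DESeq2 they were 154, 79 and 75, with voom and sample quality weights 137, 61 and 76, and with robust dispersion 56, 35 and 21. With the replicate block they were 537, 171 and 366. The replicate numbers are not said to pair the animals. The block also leaves Sirt7 scKO replicate 4, the only library of its number, out of the contrast. At an adjusted p of 0.1 the counts were 80, 48 and 32. A fold threshold of 1.2 left 2, 2 and 0 (Ibsp and Mmp13). Protein-coding genes alone gave 5, 3 and 2, as did copies added to parent genes, both with Ibsp, Mmp13, Alpl, Gdf15 and H2-Q1, which follows for the pseudogenes from their removal. For the other changes the cause was not tested.

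Without 1 library, totals ran from 0 to 330, higher from 0 to 132 and lower from 0 to 198. They were 2 without control replicate 1 (Mmp13 and, named after its value was seen, Sfrp4), 0 by edgeR without control replicate 2 (1399 at an unadjusted p under 0.05, no other tool run), 56 without control replicate 3, and 184, 21, 7 and 330 without Sirt7 scKO replicates 1 to 4. Of the 22 genes, 14 were shared without control replicate 3, 15 and 7 without Sirt7 scKO replicates 2 and 3, and 22 without Sirt7 scKO replicate 1 or 4. The Sirt7 log2 fold change ran from -0.56 to -0.25 over 19 alternatives of scaling, filter, test, dispersion, block, gene set and left-out library, and passed in 0 of them (edgeR, voom and DESeq2 adjusted p from 0.0576 to 0.713). Over the same 19, Ibsp and H2-Q1 passed in 17, Mmp13 in 17, Alpl and Gdf15 in 16, and mt-Tk in 10 of 18. The fold threshold of 1.2 and the adjusted p of 0.1 are not among the 19, and at the fold threshold Alpl, Gdf15, H2-Q1 and mt-Tk did not pass. Actn3 and Tppp3 passed in 10, mt-Ti in 10 of 18 and Dapk3 in 7. Lists past the threshold were 12 with camera's preset correlation, 0 with its estimated correlation (0 at an unadjusted p under 0.05), and 0 to 2 by fry without 1 library, the 2 being neutrophil and immediate early genes without Sirt7 scKO replicate 4.

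Signs reversed for the following values, none of them past the threshold in the main test, and the cause was not tested. Hadhb, at 0.22 in the main test, was -0.125 with copies added to parent genes. With the replicate block the medians were 0.0182 for monocyte and macrophage, -0.00204 for tenocyte and -0.000669 for growth factor genes, and with upper-quartile scaling 0.00223 for pro-inflammatory cytokine and 2.15e-05 for cytosolic ribosomal protein genes. Without 1 library, log2 fold changes ran from -0.174 to 0.043 for Myod1, -0.427 to 0.62 for Plin4 (0.41 with all libraries) and -0.474 to 0.03 for Thbs4 (-0.28 with all libraries). List medians ran from -0.0391 to 0.017 for monocyte and macrophage, -0.218 to 0.0285 for dendritic and mast cell, -0.122 to 0.148 for pro-inflammatory cytokine, -0.0131 to 0.0698 for extracellular matrix, -0.0122 to 0.11 for endothelial, -0.0596 to 0.118 for adipocyte and -0.101 to 0.0343 for Schwann and nerve genes. They ran from -0.0975 to 0.176 for tenocyte, -0.0876 to 0.05 for cytosolic and -0.0518 to 0.0273 for mitochondrial ribosomal protein, -0.0247 to 0.0749 for fatty acid oxidation, -0.135 to 0.00733 for autophagy and atrophy, and -0.0476 to 0.0826 for growth factor genes. Of the other values for named genes and lists, 2878 kept direction and side of the threshold, 195 gained the threshold and 20 lost it. Depth limits genes such as Ibsp, with 3 counts over the control libraries.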

Other observations

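The osteoclast list and the division of mitochondrial tRNA genes by strand were chosen only after the results were seen. In the osteoclast list 5 of 9 tested genes were positive, with a median log2 fold change of 0.41 (95% bootstrap interval -0.10 to 0.76) and a two-sided exact permutation p of 0.2 for its score. None passed over all genes. Its protease genes Mmp9, which the neutrophil list also holds, Ctsk and the phosphatase gene Acp5 had log2 fold changes of 0.94, 0.41 and 0.70 (edgeR adjusted p = 0.13, 0.135 and 0.151). Macrophages also express several of these genes.

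Of the 22 mitochondrial tRNA genes tested, 16 had a positive log2 fold change, with a median of 0.25. Beside mt-Tk and mt-Ti, and named after their values were seen, mt-Tg (log2 fold change 1.19) and mt-Td (1.81) each had an edgeR adjusted p of 0.0519. The 14 tRNA genes on the plus strand had a median of 0.71 and the 8 on the minus strand of -0.03, a difference with a permutation p of 0.0518 over genes, which are not independent replicates. The strand is that of the annotation, and the libraries do not mark it, so reads of either strand can be counted at these genes. The genes are 59 to 75 bases long, and whether their reads came from longer transcripts over them was not tested. Mitochondrial protein-coding genes were positive in 10 of 13 cases with a median of 0.12. Mitochondrial tRNA took 0.0973 ± 0.00252% of counts in control and 0.114 ± 0.0113% in Sirt7 scKO (two-sided exact permutation p = 0.0857), and processed pseudogenes 13.2 ± 0.0998% and 13.9 ± 0.431% (two-sided exact permutation p = 0.0571). Protein-coding genes took 82.1 ± 0.133% and 81.2 ± 0.433% (two-sided exact permutation p = 0.0571). The groups did not overlap in the share of processed pseudogenes or in that of protein-coding genes (81.936 to 82.171% in control, 80.727 to 81.757% in Sirt7 scKO). The first principal component of log2 CPM, with 31.7% of the variance, stood at -29.9, -24.5 and -4.44 in control replicates 1 to 3 and at 2.87, 26.6, 22.3 and 7.06 in Sirt7 scKO replicates 1 to 4. On the second, with 18.8% of the variance, Sirt7 scKO replicate 4 stood apart at -35.25, against -0.68 to 16.8 in the other 6 libraries.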
